A study of Mus musculus with 20 samples.

How the data were processed

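RNA from 4 blood cell populations of female mice was measured on 20 Affymetrix Mouse Gene 1.0 ST arrays. Per the labels, cells from bone or spleen were sorted by flow cytometry, RNA was extracted with Trizol, and it was amplified and labelled with the NuGEN Ovation Pico WTA v2 system. The tissue of each sample is not given in the sources used here. The deposited table holds log2 expression values for 35556 probe sets with 0 missing values. Per the submitters' processing notes the authors used RMA and the affy package, whose versions are not given in the sources used here. RMA corrects background, equalises the distributions of the arrays and summarises the probes of a set, so differences between arrays in total RNA or overall signal were removed before deposit. The array medians lay between 5.86 and 6.02. Arrays give no counts, and their number limits the precision.

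Probe sets were named from the platform annotation. It gave 1 gene symbol for 21789 probe sets and several for 1621, and 12146 probe sets were not listed in it. Probe sets with several symbols were not named. Of the single-symbol sets, 21698 were matched by Entrez identifier to the RefSeq genes of the GRCm38.p6 assembly, which was used for names, chromosomes and the order of neighbouring genes, with no coordinates printed. Each of 19938 genes was represented by its probe set with the highest mean over all arrays, and 999 genes had more than 1 probe set. A gene was tested when its mean in at least 1 cell type was above the median of all values (5.92 on the log2 scale), which left 11670 genes.

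Each sample was placed by its labels in a cell type, genotype and age, and each such combination held 1 array. All tests across genes were run with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). Heterozygous and wild-type arrays were compared within the 8 combinations of cell type and age, with 7 residual degrees of freedom. The same 16 arrays were used for the effect within each cell type (4 residual degrees of freedom), for the interactions of genotype with cell type and with age, and for 6 against 2 months. The 4 homozygous arrays were compared with the 8 wild-type and the 8 heterozygous arrays with cell type as a block (7 residual degrees of freedom). Homozygous mice were 12 months old and the others 2 or 6 months, so genotype and age cannot be told apart in those comparisons. The labels do not say whether the 4 cell populations of an age and genotype came from the same mouse. The p-values therefore measure only the spread between these samples, and they are too small if arrays share a mouse. Mutant mice carry a crossed background label and wild-type mice a 129Sv/Jae label, except the 2-month wild-type erythroid sample, which carries the crossed label.

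The 41 gene lists covered markers of the sorted and of other cell types, the cell cycle, stress and interferon responses, metabolism, chromatin, leukemia genes and X-linked genes. They and the set of all 324 tested X-linked genes other than Xist were tested with limma's camera at a preset correlation of 0.01. The estimated correlation and fry were alternatives. The Y-linked list had no member above the filter and was not tested. The X-linked shift is the median log2 difference of X-linked genes minus that of autosomal genes in each combination, with Xist left out, tested with an exact two-sided sign-flip test. The comparisons, lists, list tests, rule for named genes and most alternatives were chosen before the data were examined. The runs without the erythroid arrays, the Xist level after normalization within each cell type, and the tests of the granule genes and of the genes apart in homozygous cells were chosen after the data were seen.

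The named genes were Xist in every comparison and, over the cell types, up to 10 higher and 10 lower genes with the largest difference among those that passed with the same sign in every cell type and age. Where fewer than 5 of a direction passed, genes of the same sign throughout with the smallest p filled up to 5 and are given as not passing. Within a cell type up to 5 of each direction were taken by the same rule, and for interactions the 5 with the smallest p. Up to 4 members with the largest test statistic were taken from each list that passed camera and from the X-linked lists, and up to 4 members with the highest mean from each marker list.

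Alternatives changed the filter, the summary of probe sets, the centring of arrays, the normalization within cell types, the variance model, the treatment of age, and the arrays included. The model fits were tested on simulated data with 11670 genes, of which 100 were changed by 1 and 100 by 2 on the log2 scale. The simulated noise was independent between genes and arrays, while the real arrays may share mice. A comparison with fewer changed genes faces a stricter adjusted threshold, so the shares below may be too high for the real data. For heterozygous against wild type, 92% of genes changed by 1 on the log2 scale and 99% of those changed by 2 were recovered, with 13 false calls. For homozygous against wild type these were 84% and 98%, with 10 false calls, and for heterozygous against wild type in B cells 35% and 80%, with 4 false calls.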

Results

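Mice with a conditional Xist allele were crossed to Vav-Cre mice, so that Xist, the noncoding RNA of X inactivation, was deleted in blood cells. Gene expression was measured in B220+ B cells, CD11b+ myeloid cells, LSK CD34- hematopoietic stem cells and Ter119+ erythroid cells. Wild-type and heterozygous females were sampled at 2 and 6 months and homozygous females at 12 months, with 1 array per cell type, genotype and age and 20 arrays in all. The sample titles give the Xist genotypes as 2lox/+ for wild type, 2lox/- for heterozygotes and -/- for homozygotes. The animals called wild type therefore carried a 2lox allele too. The question was which genes change in blood cells that lack Xist.

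As means over their 5 arrays, the sorted populations were higher for most of their own markers. B cell arrays were higher than the mean of the other cell types for 19 of 19 B cell markers, among them the receptor component Cd79b (log2 difference 2.16, SE 0.209, adjusted p = 1.71e-06). In myeloid arrays 34 of 36 neutrophil and monocyte markers were higher, such as the lysozyme gene Lyz2 (2.62, SE 0.231, adjusted p = 2.77e-07). Stem cell arrays were higher for 19 of 21 stem cell markers, with Adgrg1 at 4.76 (SE 0.313, adjusted p = 8.27e-09). Erythroid arrays were higher for 18 of 19 erythroid markers, including the carbonic anhydrase Car1 (2.63, SE 0.335, adjusted p = 0.000235).
Single erythroid arrays were not all above the other cell types. The erythroid marker mean on erythroid arrays was 8.87 and 7.99 in wild type at 2 and 6 months, 6.50 and 10.31 in heterozygotes, and 7.64 in the homozygote, while the arrays of other cell types reached 7.98 (myeloid cells of heterozygotes at 6 months). B cell markers on the same arrays averaged 9.34, 9.83, 9.71, 7.47 and 8.11. On B cell arrays the precursor B list averaged 5.98, 6.02 and 6.11 in wild type at 2 and 6 months and heterozygotes at 2 months, against 9.08 in heterozygotes at 6 months and 7.99 in the homozygote. Y-linked genes stayed between 3.45 and 3.74 on every array.

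Xist, the targeted gene, was lower in heterozygotes and lowest in homozygotes. Whether its probe set lies in the deleted part is not given in the sources used here, so its level does not separate deletion of the probed sequence from loss of the transcript. Its log2 level was 10.55 ± 0.47 (SD, n = 8) in wild type, 8.81 ± 0.66 (n = 8) in heterozygotes and 5.03 ± 0.25 (n = 4) in homozygotes, where it lay below the median of all values (5.92). Heterozygous arrays were lower in 8 of 8 combinations of cell type and age, with a mean difference of -1.73 ± 0.60 (SD), or 30.1% of wild type (exact sign-flip p = 0.00781, the smallest possible). The differences ran from -2.25 to -0.42, and the smallest was in erythroid cells at 2 months. The homozygous signal was 2.19% of the wild-type one (log2 difference -5.51 ± 0.50, SD, n = 4; exact p = 0.125, the smallest possible). Against heterozygotes the log2 difference was -3.78 (limma adjusted p = 0.000682). If the homozygous signal is background, these differences are lower bounds in size and 2.19% is an upper bound.

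**Figure D1:**
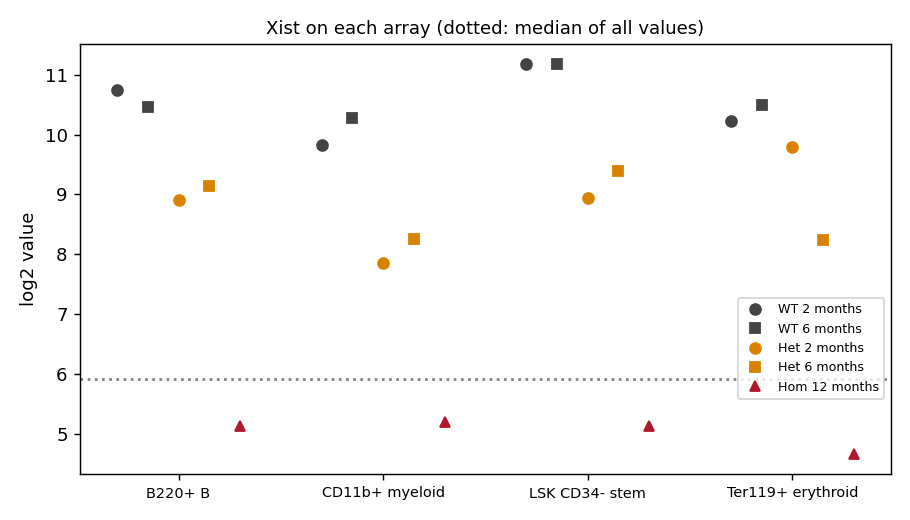
The log2 Xist value of each of the 20 arrays, by cell type, with the genotype as colour, the age in months as symbol and a dotted line at the median of all values. Wild-type arrays lie between 9.82 and 11.18, heterozygous arrays between 7.85 and 9.80, and homozygous arrays between 4.66 and 5.20.

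In heterozygous against wild-type cells, Xist was the only gene of 11670 that passed the test (0 higher and 1 lower, limma adjusted p = 0.0251 for Xist). The other genes named by the fixed rule did not pass: Mx2, an interferon-induced GTPase, was higher in 8 of 8 combinations (0.59, SE 0.079, adjusted p = 0.0927), as was the X-linked gene 1810030O07Rik (0.71, SE 0.102, adjusted p = 0.102). Rassf4 (0.52, adjusted p = 0.287), 1700056E22Rik (0.60, adjusted p = 0.287) and the interferon regulator Irf7 (0.33, adjusted p = 0.305) were also higher in all 8. Lower in all 8 were the glucose transporter Slc2a3 (-0.56, adjusted p = 0.0927), Ly6k (-0.55, adjusted p = 0.287), the Polycomb gene Pcgf2 (-0.35, adjusted p = 0.668) and the chromatin remodeller Chd7 (-0.55, adjusted p = 0.668). At an unadjusted p under 0.05 there were 841 genes, 385 higher and 456 lower. The Xist call was lost, with adjusted p from 0.0821 to 0.16, when any combination other than erythroid cells at 2 months was left out, and without that pair the adjusted p was 0.000265. It was also lost with age and genotype as a random block (adjusted p = 0.139) and with averages over cell types (adjusted p = 1). Both fits allow for arrays sharing a mouse. The averages leave 1 value per age and genotype, so that fit could hardly call any gene. The Xist call was lost too with trend and robust variances (adjusted p = 0.738), and with 2 or 6 months alone (adjusted p = 0.945 and 0.0974).
Among gene groups the interferon list stood out. Its 25 members were higher in 23 cases, with a median of 0.39 and a list mean higher in 8 of 8 combinations, and 15 were higher adjusted over the list alone against 0 over all genes. The list passed limma's camera (adjusted p = 2.83e-15), an estimated correlation (adjusted p = 0.024) and fry (adjusted p = 0.00467). These tests treat the combinations as separate mice, so their p-values are too small if arrays share a mouse. In wild type alone the list mean changed from 2 to 6 months by -0.39, -1.18, -0.20 and -0.39 in B, myeloid, stem and erythroid cells. Genotype cannot be told apart from the background label, which differed between the genotypes in all but the 2-month erythroid pair. Rtp4 (0.55) and Ifi27l2a (0.64) were among the members that did not pass singly (adjusted p = 0.492 and 0.616). Without the erythroid arrays 23 of 25 members were still higher (median 0.34), and the list passed camera (adjusted p = 6.26e-11) and fry (adjusted p = 0.0467) but not an estimated correlation (adjusted p = 0.337).
Of the other lists, 19 passed camera at the preset correlation and none held with an estimated correlation. All 23 genes of the G2 and M phase list were higher (median 0.59; camera adjusted p = 5.66e-09, adjusted p = 0.569 with an estimated correlation), with Aurkb at 0.50 and Bub1b at 0.66. Its list mean differed by 0.34, -0.47, 0.30 and -1.23 in B, myeloid, stem and erythroid cells at 2 months. At 6 months it differed by 2.31, 0.88, 1.03 and 1.51 in the same order. The S phase list was higher for 22 of 23 (0.31; camera adjusted p = 0.000343, adjusted p = 0.712 with an estimated correlation), with the helicase subunit Mcm5 at 0.41. Its list mean was lower in myeloid and erythroid cells at 2 months (-0.23 and -1.24) and higher in the other 6 combinations. Monocyte markers were higher for 15 of 16 (median 0.54; camera adjusted p = 9.99e-06, adjusted p = 0.569 with an estimated correlation), and Cd68 was at 0.54. Their list mean differed by -0.32, 0, 0.10 and -0.14 at 2 months and by 1.32, 1.68, -0.08 and 0.92 at 6 months, in B, myeloid, stem and erythroid cells. Plasma cell markers were lower for 10 of 10 (median -0.78; camera adjusted p = 4.97e-07, 0.569 with an estimated correlation), and 6 of them adjusted over the list alone. T and NK cell markers were lower for 16 of 16 (median -0.54, Cd3e -0.54), and B cell markers for 17 of 19 (median -0.44, Cr2 -1.64), with adjusted p = 0.569 and 0.663 under an estimated correlation. MHC class II genes were lower for 8 of 8 (-0.43; 0.569 under an estimated correlation). Beside these groups, the B cell marker mean on myeloid arrays was 8.18 and 9.01 in wild type and 8.12 and 6.88 in heterozygotes at 2 and 6 months, and that of T and NK cell markers 7.81, 8.20, 8.08 and 6.43. Lower by camera too were unfolded protein response (-0.19), neutrophil (-0.44), stem cell (-0.13) and immediate early genes (-0.15). Precursor B genes (0.38), oxidative phosphorylation (0.10), erythroid markers (0.30), heme synthesis (0.25) and NF-kB genes (0.11) were higher by camera. The precursor B list mean differed by 3.05 in B cells at 6 months and by -0.14 to 0.40 in the other combinations. The erythroid list mean was lower in all 4 cell types at 2 months (-0.16 to -2.37) and higher in all 4 at 6 months (0.48 to 2.32). Without the erythroid arrays neutrophil (-0.15, camera adjusted p = 0.212) and immediate early genes (-0.06, adjusted p = 0.168) no longer passed, no plasma cell marker passed over the list alone, and the medians were -0.26 for B cell markers, -0.26 for MHC class II, -0.12 for unfolded protein response, 0.17 for oxidative phosphorylation, 0.53 for erythroid markers and 0.10 for X-linked blood genes, while ribosome biogenesis genes passed camera (0.08).

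X-linked genes were compared as a group because Xist silences the X chromosome. In heterozygous cells the X-linked shift was 0.0466 ± 0.0507 (SD, n = 8), above 0 in 6 of 8 combinations (exact sign-flip p = 0.0469), from -0.0266 in erythroid cells at 2 months to 0.127 in B cells at 6 months. It was 0.045 ± 0.0366 in homozygous cells (n = 4), above 0 in 4 of 4 cell types, where the smallest exact p is 0.125, and 0.028 without the erythroid array. With no filter on dim genes the shifts were 0.02 in heterozygotes and 0.0255 in homozygotes, and with the stricter filter 0.081 and 0.0836 (exact p = 0.00781 in heterozygotes with either). At an unadjusted p under 0.01, 10 of 324 X-linked genes (3.09%) and 66 of 11305 autosomal genes (0.584%) were higher in heterozygotes, and 27 (8.33%) and 330 (2.92%) in homozygotes. Genes that escape X inactivation were higher in heterozygotes for 7 of 9 (median 0.22; camera adjusted p = 0.000974, adjusted p = 0.563 with an estimated correlation), such as Pbdc1 (0.45), Utp14a (0.41), Kdm5c (0.25) and the helicase Ddx3x (0.26). X-linked blood genes were higher for 21 of 30 (median 0.05; 0.00345 and 0.289), with the largest test statistics for the RNA sensors Tlr7 (0.66) and Tlr8 (1.10), Msn (0.20) and Pgk1 (0.35). Alas2, a member that is also an erythroid marker, was at 1.24 (SE 0.573). None of these single genes passed the test. The set of all X-linked genes was higher by camera (median 0.05, adjusted p = 0.00303), with an adjusted p = 0.563 under an estimated correlation. In homozygotes X-linked genes did not pass camera as a set (adjusted p = 0.152). The heterozygous shift no longer passed in 6 of 8 runs that left out 1 combination, nor without the erythroid arrays (0.0589, exact p = 0.0625).

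Within single cell types no gene passed in limma (0 in B, myeloid, stem and erythroid cells), and 215, 353, 243 and 557 genes had an unadjusted p under 0.05. Xist was -1.58, -2.00, -2.01 and -1.34 in these cell types. In B cells the progenitor receptor Cd93 was 2.41 higher (1 at 2 months and 3.82 at 6 months). In myeloid cells Smpdl3b (1.73), Tlr8 (1.76) and Cd300e (1.93) were higher. The immunoglobulin gene Ighm (-2.34) and the plasma cell receptor Tnfrsf17 (-2.42) were lower there. The plasma cell list averaged 8.42 and 9.69 on wild-type myeloid arrays at 2 and 6 months, against 8.43 and 7.85 on wild-type B cell arrays. For Ighm and Tnfrsf17 a change in myeloid cells cannot be told apart from fewer plasma cells in the sort. In stem cells Ifi27l2a (1.18) and Cpa3 (1.35) were higher and Fosb (-1.36) and the stem cell regulator Mecom (-0.86) lower. In erythroid cells Smpdl3b (1.47) was higher and Fosb (-1.33) and the neutrophil chemokine receptor Cxcr2 (-2.29) lower. The neutrophil list averaged 9.06 and 7.89 on wild-type erythroid arrays at 2 and 6 months, against 7.17 and 7.7 in heterozygotes. For Cxcr2 a change in erythroid cells cannot be told apart from fewer neutrophils in the sort. By camera, G2 and M phase genes (1.34) and precursor B genes (1.90) were higher in B cells, plasma cell markers lower in myeloid cells (-1.69), and stem cell markers lower in stem cells (-0.37), with adjusted p = 0.646, 0.646, 0.605 and 0.433 under an estimated correlation. The 2 ages differed in size. In this order the list means differed by 0.34, 0.13, -0.68 and -0.26 at 2 months and by 2.31, 3.05, -2.61 and -0.56 at 6 months. No gene differed in its response between cell types in limma (0 genes, 146 at an unadjusted p under 0.05).

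**Figure D2:**
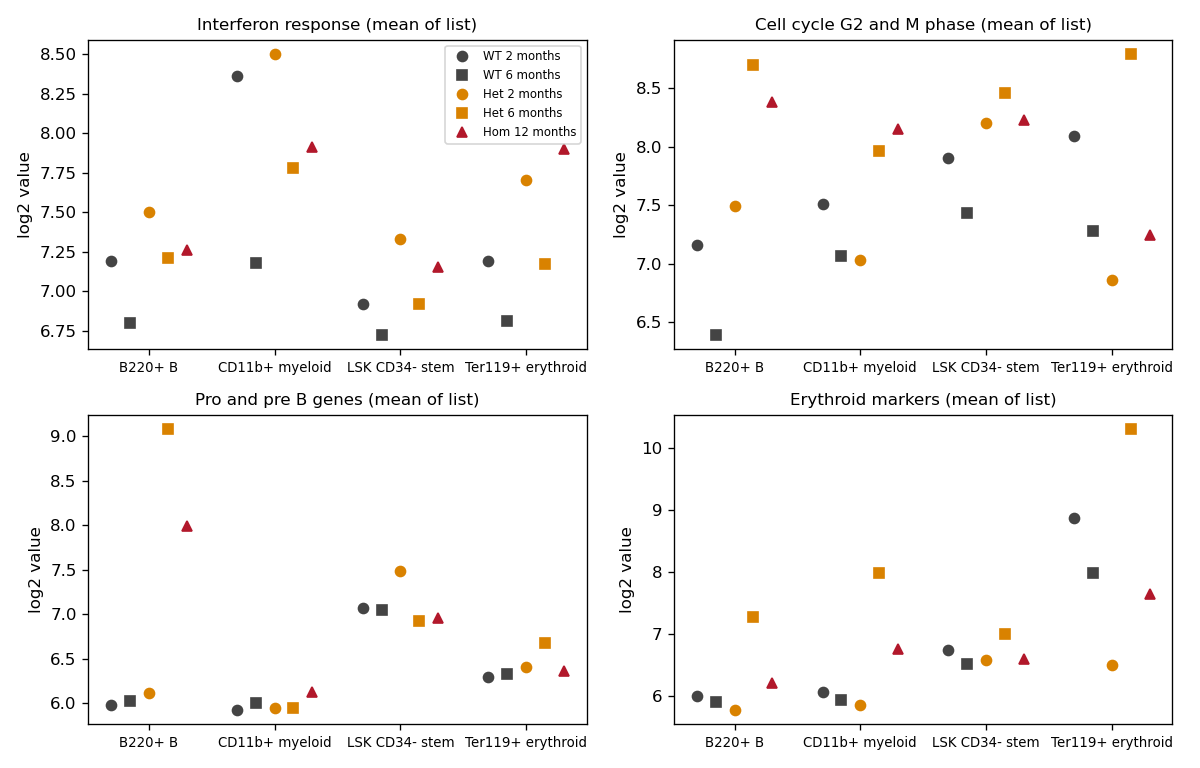
Mean log2 value of the interferon, G2 and M phase, precursor B and erythroid marker lists on each of the 20 arrays, by cell type, with the genotype as colour and the age in months as symbol. In B cells the precursor B list stands at 9.08 in heterozygotes at 6 months and 7.99 in the homozygote, against 5.98 to 6.11 on the other arrays.

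The effect of genotype was compared between 2 and 6 months. No gene passed in limma (0 genes), while 2209 had an unadjusted p under 0.05, 1423 with a more positive and 786 with a more negative effect at 6 months. The lowest adjusted p values were those of Snord14e (-1.27, adjusted p = 0.0575), Chrnb1 (-1.10) and the mitotic genes Ska3 (1.86), Trip13 (1.14) and Kif22 (1.41), the last 4 at adjusted p = 0.144. All 23 G2 and M phase genes had a more positive effect (median 1.69, Ccnb2 1.95), 23 of them adjusted over the list alone, and so had 22 of 23 S phase genes (1.14, Rrm2 2.35), 21 over the list alone. Erythroid markers moved the same way for 19 of 19 (2.31, Car1 3.80, Klf1 1.79), 17 over the list alone, and their mean on erythroid arrays was 6.50 in heterozygotes at 2 months and 10.31 at 6 months. Oxidative phosphorylation (0.51), monocyte (1.16), neutrophil (1.14) and heme synthesis genes (1.29) were also more positive by camera, and B cell (-1.17), T and NK cell (-0.82), MHC class II (-0.67) and plasma cell genes (-0.67) more negative. These 11 lists passed camera (adjusted p = 1.81e-17 for G2 and M phase) and none passed with an estimated correlation (lowest adjusted p = 0.773). Without the erythroid arrays all 11 still passed camera, with medians of 0.72 for S phase (1 gene over the list alone), 0.44 for heme synthesis, 1.31 for erythroid markers, 1.40 for G2 and M phase (21 genes), 0.33 for oxidative phosphorylation, -0.76 for B cell, -0.52 for T and NK cell and -0.22 for MHC class II genes. Heat shock (-0.24, camera adjusted p = 0.00202, 3 genes lower over the list alone) and stem cell genes (-0.21, adjusted p = 0.023) then passed camera as well. Without the stem cell pair at 6 months 62 genes passed, 37 more positive and 25 more negative.

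At 6 months, compared with 2 months, interferon genes were lower in both genotypes. Mx2 (-0.82, SE 0.094, adjusted p = 0.0524), Ifi27l2a (-0.79, adjusted p = 0.0747), Oas2 (-1.11, adjusted p = 0.133), Ifit1 (-0.94, adjusted p = 0.144) and Rtp4 (-1.10, adjusted p = 0.309) were lower in 8 of 8 pairs and did not pass. No gene passed in limma (0 genes, 773 at an unadjusted p under 0.05, 272 higher and 501 lower), and Xist had an adjusted p = 0.998. Of the interferon list, 22 of 25 members were lower (median -0.52), 19 adjusted over the list alone (camera adjusted p = 1.63e-21, adjusted p = 0.172 with an estimated correlation, fry adjusted p = 0.0335). Immediate early genes were lower for 18 of 18 (-0.47; Fos -1.03, Junb -0.65), 10 over the list alone, and NF-kB genes for 17 of 18 (-0.32; Tnf -0.57), both at adjusted p = 0.172 with an estimated correlation. Erythroid markers were higher for 19 of 19 (0.84, Alas2 1.28; camera adjusted p = 2.38e-07, adjusted p = 0.699 with an estimated correlation). Their mean was lower in all 4 wild-type pairs (-0.09, -0.13, -0.23 and -0.88 in B, myeloid, stem and erythroid cells). It was higher in all 4 heterozygous pairs (1.51, 2.13, 0.41 and 3.82), so the genotypes did not share this rise. Stmn3 (0.29), Ssbp1 (0.35), Znhit3 (0.31), Pfkfb2 (0.30) and Haus6 (0.33) were higher in 8 of 8 pairs and did not pass. A further 11 lists passed camera, and none of them passed with an estimated correlation (adjusted p from 0.699). Without the erythroid arrays the interferon and NF-kB lists no longer passed fry (adjusted p = 0.132 and 0.0944), and B cell, monocyte, S phase and G2 and M phase genes no longer passed camera, while DNA repair genes did (0.06).

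Homozygous cells at 12 months differed from wild type for 40 genes, 20 higher and 20 lower. Genes of neutrophil primary granules rose in every cell type: the protease Ctsg (log2 difference 1.85, SE 0.133, adjusted p = 0.000248), Prtn3 (1.56, SE 0.136, adjusted p = 0.000781), the peroxidase Mpo (1.45, SE 0.195, adjusted p = 0.0221) and Elane (1.20, SE 0.208, adjusted p = 0.0462). The Fc receptor Fcgr4 (2.58), AI506816 (1.87), Ms4a3 (1.58), Gdpd3 (1.36), the cell cycle inhibitor Cdkn2c (1.03) and the X-linked glycolytic enzyme Pgk1 (0.94) rose as well. Fcgr4 in stem cells (5.67 against 5.12 and 5.05) and Ms4a3 in B cells (5.43 against 4.78 and 4.21) stayed below the median of all values. In heterozygotes Fcgr4 differed by 0.05, 0.48, 0 and 2.78 at 2 months in B, myeloid, stem and erythroid cells. At 6 months it differed by 4.61, 3.57, 0.16 and 2.73 in the same order. Xist fell by 5.51 (adjusted p = 7.94e-08), BC018473 by 3.32 (SE 0.274, adjusted p = 0.000645), the sialyltransferase St6galnac2 by 1.39 (SE 0.126, adjusted p = 0.000995), the phosphatase Inpp4b by 1.22 and the X-linked G530011O06Rik by 1.03. Sesn3 (-0.89), Prag1 (-0.79), the chaperone Hsph1 (-0.78), Zfp827 (-0.74) and Gm7265 (-0.74) fell too. Homozygous arrays had BC018473 at 4.86 to 5.53, G530011O06Rik at 5.18 to 5.37 and Gm7265 at 4.92 to 5.68. These levels lie below the median of all values (5.92), like those of Xist. The falls of these genes and of Xist are therefore lower bounds if that signal is background. The adjusted p of the genes without a stated one were 0.0221 to 0.0485 in limma. The neutrophil list as a whole was higher for 14 of 20 members (median 0.25), 4 of them over all genes and 4 adjusted over the list alone (camera adjusted p = 0.00844, adjusted p = 0.636 with an estimated correlation).
B cell markers were lower for 18 of 19 (median -0.70, Cr2 -2.02), 11 adjusted over the list alone (adjusted p = 0.569 with an estimated correlation). T and NK cell markers were lower for 16 of 16 (-0.89, Cd4 -0.73), 11 over the list alone, plasma cell markers for 10 of 10 (-0.92, Jchain -2.34) and MHC class II genes for 8 of 8 (-0.63), all at an adjusted p = 0.569 with an estimated correlation. Monocyte markers were higher for 15 of 16 (0.80, C1qb 1.54), 10 over the list alone, and G2 and M phase genes for 23 of 23 (0.62, Ccnb2 0.94), with adjusted p = 0.569 and 0.607. Oxidative phosphorylation (0.19, Cox5a 0.58, adjusted p = 0.0451) and glycolysis genes (0.34, Ldha 0.67, adjusted p = 0.0967) were higher, and of heat shock genes Dnaja1 (-0.42) and Hsph1 passed. Interferon (0.38), S phase (0.30) and precursor B genes (0.56) were higher and unfolded protein response (-0.07) and stem cell genes (-0.22) lower by camera, and none of the 15 lists held with an estimated correlation (adjusted p from 0.569). Beside the lymphoid lists, B cell markers averaged 7.10 on the homozygous myeloid array, against 8.18 and 9.01 in wild type. The list means differed between cell types: B cell markers by -0.02, -1.49, 0.01 and -1.47 in B, myeloid, stem and erythroid cells, G2 and M phase genes by 1.61, 0.86, 0.56 and -0.44, and S phase genes by 0.95, 0.57, 0.36 and -0.72. Precursor B genes differed by 1.99, 0.17, -0.11 and 0.05 in the same order. Without the erythroid arrays all 15 lists still passed camera, with medians of -0.45 for B cell markers, 0.38 for monocyte markers (0 genes over the list alone for each), -0.60 for T and NK cell markers (7), -0.45 for MHC class II (0), 1.05 for G2 and M phase (21, against 0 with all arrays) and 0.64 for S phase genes (21, against 0), 0.13 for neutrophil and -0.17 for unfolded protein response genes, and erythroid markers passed camera as well (0.30).

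**Figure D3:**
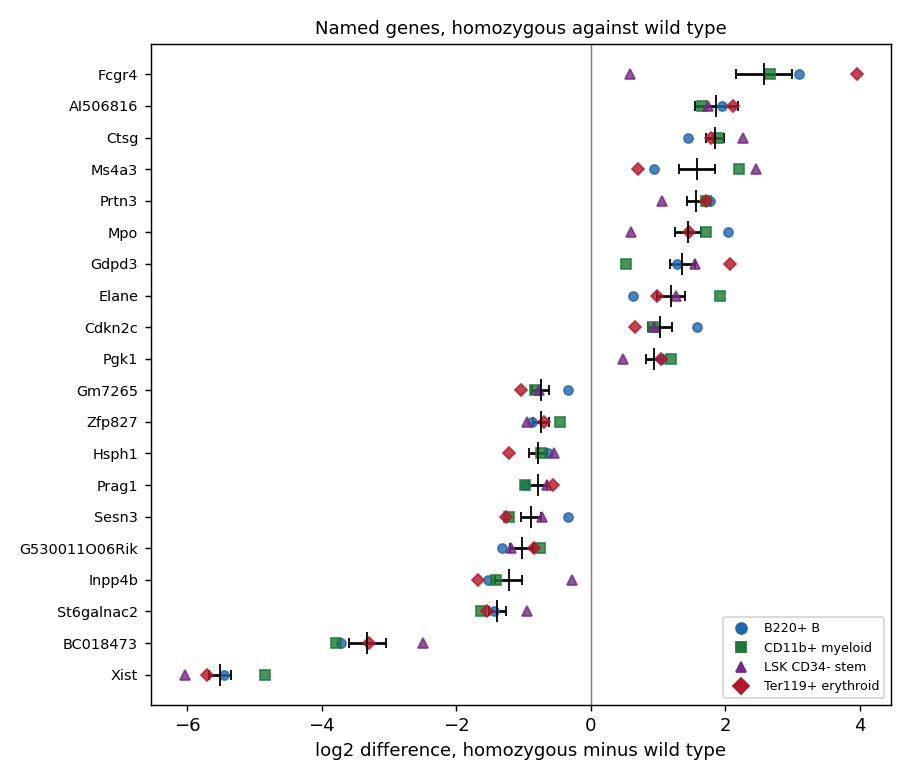
Log2 difference of the homozygous array from the wild-type mean in each of the 4 cell types (coloured points), with the fitted difference and its standard error (black), for the 20 named genes. Xist lies lowest, at -5.51, and Fcgr4 highest, at 2.58.

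Arrays centred on their medians gave 9 higher and 4 lower genes. Against the 2-month wild types alone 2 genes passed (Xist and BC018473), and against the 6-month ones 2 (Xist and AI506816), so no granule gene passed against either age alone. With age as a linear covariate 11 genes passed, 2 of them among the 40, and Ctsg was at 0.34 (adjusted p = 0.959). Leaving out the B cell, myeloid, stem or erythroid arrays gave 6, 6, 24 or 13.

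Against heterozygotes, homozygous cells differed in 3 genes. AI506816 rose by 1.95 (SE 0.173, adjusted p = 0.00148), and BC018473 (-3.09, SE 0.237, adjusted p = 0.000682) and Xist (-3.78, SE 0.297, adjusted p = 0.000682) fell in 4 of 4 cell types in limma. Gdpd3 (1.44, adjusted p = 0.0933), Trappc4 (0.45), Ltb4r1 (0.69) and the X-linked Nxt2 (0.66) were higher and St6galnac2 (-1.27, adjusted p = 0.16), G530011O06Rik (-0.99, adjusted p = 0.189) and Arl3 (-0.68, adjusted p = 0.398) lower in 4 of 4 cell types without passing. The falls of Xist, BC018473 and G530011O06Rik are lower bounds here too if their homozygous signal is background. At an unadjusted p under 0.05 there were 352 genes. Neutrophil markers were higher for 18 of 20 (median 0.63, Elane 1.13, Mpo 1.34; camera adjusted p = 1.1e-12) and glycolysis genes for 13 of 15 (0.27), both at adjusted p = 0.389 with an estimated correlation. A further 10 lists passed camera, and none of them passed with an estimated correlation (adjusted p from 0.594). Without the erythroid arrays 4 of these 12 lists still passed camera, among them neutrophil markers (0.33) and glycolysis genes (0.11), and S phase (0.23), G2 and M phase (0.30) and unfolded protein response genes (-0.16) passed as well.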

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

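The tests of the granule genes and of the genes apart in every homozygous cell type were chosen only after those results were seen, and the others were planned. Of 27 groups of arrays searched for a value far from the rest, chance alone gives about 1 in 20. Among the 5 B cell arrays, that of heterozygotes at 6 months stood apart for the B cell marker mean (10.4, the lowest) and for the erythroid marker mean (7.28, the highest). The other B cell arrays had B cell marker means of 10.49 to 10.52, so that difference was small. Their erythroid marker means were 5.77 to 6.21, and the gap was 0.711 of the range, barely past the critical 0.71. Among 5805 tested probe sets without a listed gene, 7 passed in homozygous against wild type, all lower, and 0 in heterozygous against wild type in limma (381 at an unadjusted p under 0.05).

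Primary granule genes were higher in all 4 homozygous cell types (1.47 in B, 1.81 in myeloid, 1.30 in stem and 1.49 in erythroid cells as the mean of 4 genes), and in heterozygous cells they differed by 0.70, 1.09, 0.64 and 0.96 at 6 months and by 0.01, -0.90, 0.55 and -1.28 at 2 months, in the same order of cell types. Mature neutrophils mixed into the sorts stay open. The median difference of 8 mature neutrophil genes was 0.08 (SD 0.24), below the 1.20 of the lowest granule gene, but it pools cell types that differed. In B cells S100a8, S100a9 and Camp differed by 0.94, 0.88 and 0.89, but Ly6g, Mmp8 and Mmp9 by -0.56, -0.47 and -0.34. In stem cells S100a8, S100a9 and Camp differed by -1.58, -2.28 and -1.5. S100a8 stood at 13.09 and 12.97 on the wild-type myeloid arrays, whose highest values were 13.69 and 13.67, leaving little room for a rise. Marrow in place of spleen as the source stays open: the precursor B list was 1.97 above the higher wild-type B cell array, but the stem cell arrays, which a change of source was predicted to leave near the 0 between their wild types, differed by 1.30, and the tissue of each sample is not given in the sources used here. Age stays open too: wild-type mice differed by -0.03 between 6 and 2 months, and no wild-type array of 12 months was analysed here. The genotype, as the biological explanation, is untested against age.

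Genes such as BC018473, St6galnac2 and AI506816 were apart in every homozygous cell type. Mixing of the 4 sorted cell types with one another stays open. Of 39 genes, only 15 exceeded their range over the wild-type cell types. By over 2 standard errors 11 did so, these 3 among them. The bound of up to 3 by chance holds for unselected genes, and these were chosen for their difference in the same arrays. The range may also be too small, because wild-type sorts held markers of other cell types (B cell markers at 9.34 and 9.83 on wild-type erythroid arrays). Mixing with cell types not sorted here stays open too. A strain haplotype carried by the homozygous mouse would place such genes next to each other. A first version of the test, over all 38 placed genes, found 7 with a called gene among their 5 nearest tested genes on either side, above the 95th percentile of random draws (4; share 0.0026), namely BC018473 with St6galnac2 (chromosome 11), AI506816 with Rint1 (chromosome 5), and Palm, Prtn3 and Elane (chromosome 10), of which Prtn3 and Elane are granule genes that are expressed together. The test was then changed to leave out the neutrophil list, and 4 of 34 genes had such a neighbour, no more than the 95th percentile (4; share 0.0769), namely the first 2 pairs, so a haplotype may be part of the cause and cannot be told apart.

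X-linked genes were slightly higher in heterozygous cells. Mixing of the sorted cell types with one another would leave X-linked genes no higher than autosomal genes with matching cell type profiles. X-linked genes exceeded those by 0.07 (exact sign-flip p = 0.0156, above 0 in 7 of 8 combinations). This goes against such mixing but does not exclude it. The p-value is too small if arrays share a mouse, and the profiles came from wild-type sorts that held markers of other cell types. Mixing with cell types not sorted here stays open, because the profiles do not cover them. The interferon response stays open. Without 28 X-linked genes that follow the interferon list the shift was 0.0304 (exact p = 0.18). Those genes were chosen by their correlation with the list over these same arrays, and the list was itself higher in heterozygotes. Leaving them out was therefore bound to lower the shift and does not decide the question. Loss of Xist, as the biological explanation, was not tested apart from the background label of the mice.

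Other groupings of the same arrays were drawn and their genes counted. For lineage identity chance can be excluded (1 of 100 groupings as large; real 90 markers, highest other 40). For heterozygous against wild type the real grouping gave 1 gene, Xist itself, and the highest other 0 (1 of 100), which adds nothing to the Xist call. Groupings that exchange single arrays gave fewer genes than the real one for homozygous against wild type (1 of 81 as large; real 40, highest other 22) and against heterozygous (1 of 81; 3 and 1), but they treat the arrays of a cell type as separate mice. If the arrays of an age and genotype share a mouse, the groupings that keep them whole number 3 in each comparison, too few for a share under 0.05. Those gave 0 and 0 genes with a wild-type age set apart, against 40, and 1 and 0 with a heterozygous age set apart, against 3. For 6 against 2 months (100 of 100; real 0, highest other 1) and for genotype by cell type (24 of 24; 0 and 0) the real count of 0 fixes the outcome, so they decide nothing. For genotype by age the groupings were too few (8 of 8; 0 and 0).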

How the results depend on the processing

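The runs without the erythroid arrays and the Xist level after normalization within each cell type were chosen only after the data were seen, and the others were planned. Values of named genes kept their direction and side of the threshold in 633 cases, lost the call in 149, gained it in 13 and changed sign in 7. Counts and other summary values stayed the same in 97 cases, moved in 49 and lost a call in 7. The count for heterozygous against wild type was 1. It became 2 with no filter (Xist and Sva), with median-centred arrays, with quantile normalization within cell types or without the 2-month erythroid pair (Xist and Mx2 in each). It was 3 with all 20 arrays in 1 fit (1810030O07Rik, Mx2 and Xist) and 0 with trend and robust variances, a random block of age and genotype, averages over cell types, or either age alone, and 0 to 2 leaving out 1 combination. The Xist adjusted p ranged from 0.000265 to 1 over these runs. Sva and the other genes named here were chosen after their values were seen. Genotype by age moved from 0 to 1 gene, Snord14e, with no filter, the stricter filter or quantile normalization, and to 0 to 62 leaving out 1 combination, with 62 without the stem cell pair at 6 months. For 6 against 2 months, centring gave 1 gene (Mx2), quantile normalization 2 (Ifi27l2a and Mx2), and leaving out 1 pair 0 to 2: 2 without the wild-type myeloid pair (Ifit1 and Oas2) and 1 without the heterozygous B cell pair (Ifi27l2a). Homozygous against wild type moved from 40 to 13 with centring, 11 with linear age, 2 with the 2-month wild types (Xist and BC018473), 2 with the 6-month ones (Xist and AI506816), 13 without the erythroid arrays and 6 to 24 leaving out 1 cell type. Homozygous against heterozygous moved from 3 to 5 with linear age (BC018473, Ifi27l2a, Oas2, Rtp4 and Xist), 1 with the 2-month arrays (BC018473) and 5 with the 6-month arrays (AI506816, BC018473, Car1, Mt2 and Xist). The heterozygous X-linked shift lay between 0.0351 and 0.057 leaving out 1 combination and lost its call in 6 of 8 such runs (0.0351 to 0.0497), and without the erythroid arrays (0.0589). It was 0.02 with no filter and 0.081 with the stricter filter, and the homozygous shift 0.0255 and 0.0836, and 0.028 without the erythroid array. With fewer arrays the smaller number of combinations raises the smallest p. With an estimated correlation the lists passing fell from 20, 11, 15, 15 and 12 to 1, 0, 0, 0 and 0, in the order heterozygous, genotype by age, 6 against 2 months, homozygous against wild type and against heterozygous, and with fry to 1, 0, 2, 0 and 0. Homozygous against heterozygous had 7 lists without the erythroid arrays. Signs turned for Xist between ages (0.004 centred, -0.068 to 0.221 leaving out 1 pair, above 0 at 0.037 and 0.221 leaving out the wild-type B cell or the heterozygous erythroid pair, 0.213 without the erythroid arrays) and, with linear age, for Sesn3 (0.327), Prag1 (0.067) and Hsph1 (0.317). The cause was not tested. For genotype by age, a random block was not run because age and genotype are already terms of the model, and averages over cell types were not run because they leave no degrees of freedom. Other Xist probe sets were not run, since Xist had 1. The labels give no replicate numbers, so no fit used them as a block, and genotypes were compared within cell type and age. No detection calls were used here, and background signal makes differences of dim genes look smaller.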

Other observations

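The list tests here were planned, and the array correlations were chosen only after the data were seen. Lists tied to leukemia and chromatin did not pass camera in the comparisons over all cell types. In heterozygous cells the medians were -0.02 for 27 leukemia proto-oncogenes, 0.11 for 25 leukemia tumour suppressors and 0.01 for 24 Polycomb genes, and in homozygous cells -0.02, 0.06 and -0.01. Genes of Xist partners and X inactivation factors had medians of -0.03 and -0.05 over 20 genes. In heterozygous stem cells the proto-oncogene list was lower by camera (median -0.13, adjusted p = 0.0218; adjusted p = 0.433 with an estimated correlation).

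The best correlated partner of most arrays was of the same cell type. The exceptions were the homozygous erythroid array and the heterozygous myeloid array at 6 months, which were each other's best match (r = 0.984 across probe sets, which are not independent replicates). On the homozygous erythroid array monocyte markers averaged 9.49 and erythroid markers 7.64, and on the heterozygous myeloid array at 6 months 9.73 and 7.98.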
